A study of Caenorhabditis elegans with 8 samples.

How the data were processed

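RNA of whole young adult worms was sequenced in 8 libraries, 2 for each of 4 groups: wild type and hlh-30 mutants, each on S. aureus and on E. coli, heat-killed according to the protocol. Groups and replicate numbers were taken from the sample titles. Per the file headers, the authors deposited for each library a table of isoforms with FPKM (fragments scaled by isoform length and by mapped fragments), its confidence bounds and a status for each estimate, in the column layout of Cufflinks tracking files. Per the file headers the same tables hold a coverage column, which in each deposited table is FPKM times 1 constant. The submitters' processing notes name TopHat, Partek and DESeq, without versions or roles, and the genome build and annotation are not given in the sources used here. Whether reads were counted by strand is likewise not given, so reads of overlapping or antisense genes cannot be told apart.

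Each table lists 29943 isoforms of 20229 genes on 6 chromosomes, and 18722 gene identifiers matched a symbol in the gene name table used. The start and end of coding rows matched the WBcel235 annotation for 1.13% of 19180 identifiers, so no coordinate of that annotation was used. Gene FPKM was the sum over isoforms. For 12186 transcripts the tables list a coding part beside the whole transcript, and summing keeps both. The 194 genes with any of 977 isoforms whose estimate has a failed status were left out. No estimate had a too-deep status, and those marked as of low data (113 to 271 isoforms per library) were kept. Values were scaled between libraries by the median of ratios (factors 0.914 to 1.15), and 14360 genes with scaled FPKM of at least 1 in at least 2 libraries were tested.

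Read numbers were recovered from coverage. With 42 aligned bases per read and a Gaussian fragment length of mean 200 and SD 80 bases, 88.5% of 28200 low values (at most 10 reads, genes with 1 isoform row of at least 200 bases) lay within 0.1 of a whole number, where 20.0% would by chance. The aligned bases per read and the shortest fragment were chosen from the values and the mean and SD were assumed, so reads per gene are estimates. They give 10870211 to 13072238 reads on genes per library. Taken over the full length of a gene of 1 kb, 3 reads correspond to 0.223 to 0.267 FPKM, a floor that covers counting error only. The recovery of reads shortens that length to allow for the fragment length, which would place the floor higher.

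Each gene was tested with limma (version 3.58.1 in R 4.3.3; trend and empirical Bayes) on log2(scaled FPKM + 1), in 1 model over all 4 groups with 4 residual and 3.65 prior degrees of freedom. Folds are on that scale and understate changes of low genes. The contrasts were infection in wild type, infection in mutants, genotype in uninfected animals, genotype in infected animals, and the difference between both infection responses. All p-values are two-sided and adjusted by the Benjamini-Hochberg method within a contrast, at 0.05. Of 46 gene lists fixed before the data were examined (gene families of defence, detoxification, lysosome, metabolism and structure, stress responses, and markers of tissues), 45 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Adjusted p-values of lists are over the 45 lists of a contrast. Some lists share members, such as the intestine list with those of cathepsin-type proteases and of regulators, so their calls are not separate. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

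Genes named in the text follow a rule also fixed before the data were examined: hlh-30; in each contrast up to 8 genes per direction with the largest change among those called whose libraries do not overlap; for the interaction, called genes of either direction without that condition; up to 3 called members of each list with the largest change; and, for infection, the known S. aureus markers whether or not they pass. Genes outside it are said to be named after their values were seen.

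The test was tried on simulated data with the real means and spreads of the 14360 genes and 200 changed genes, picked among those with a mean above 2 on the log2 scale. For infection in wild type it recovered 37.3%, 77.6% and 93.9% of changes of log2 1, 2 and 3, with 8 false among 147 calls, and for the interaction 10.4%, 55.2% and 78.8%, with 5 false among 101. Unchanged simulated data gave no call for infection in wild type, and were not tried for the interaction. Genes and libraries were drawn independently, so the simulations held no correlation between genes and no shift of a whole library. Their false calls may therefore understate those in the real data.

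Alternatives planned beforehand were a pseudocount of 0.1, FPKM of at least 5 or no filter, FPKM as deposited or quantile normalization, failed estimates kept, single isoforms (22107 tested), the replicate number as a block, only the libraries of a contrast, and each library left out in turn. Where a library is left out, the lone library of its group is assumed to vary like the other groups. Added after the data were seen were a filter of at least 10 recovered reads in 2 libraries, voom (limma) on recovered reads, and choosing genes in 1 wild-type replicate set and measuring them in the other and in either mutant set. A named gene held its call in every alternative if it was called in each one that tested it. Single isoforms and the choice of genes in 1 set were not compared by gene. Genes of few reads were not tested in either setting on recovered reads.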

Results

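Transcript levels were measured by RNA sequencing in whole young adult Caenorhabditis elegans of 2 genotypes, wild type (the N2 strain) and mutants of hlh-30, which encodes the worm counterpart of the mammalian transcription factor TFEB, a regulator of autophagy and lysosomal genes. Animals grown at 20 °C were placed for 8 h at 25 °C on plates of Staphylococcus aureus NCTC8325, a human pathogen that infects the worm intestine, or on control plates of Escherichia coli OP50, the usual laboratory food. The labels differ on the control: the protocol has the E. coli killed by heat, while the sample descriptions call it normal feed. Infected and control animals therefore differed in bacterial species as well as in infection and, if the protocol holds, in whether the bacteria were alive. Each of the 4 groups held 2 libraries from 2 replicate sets that the labels call independent, without saying how the sets were kept apart, so p-values measure the spread between these samples. Mapped reads behind the values ranged from 11219832 to 13433320 per library. The labels state the design as a comparison of infected with uninfected animals in both genotypes, and 14360 genes were tested. The first 2 principal components held 34.8% and 29.7% of the variance. Libraries of the same group correlated at Pearson's r of 0.986 to 0.987 across genes, which are not independent replicates, and libraries of different groups at 0.961 to 0.988, so the ranges overlap. The highest value was between uninfected wild-type replicate 2 and uninfected mutant replicate 2. Uninfected and infected mutants of replicate 1 correlated at 0.9873, above every same-group pair (at most 0.9869), and those of replicate 2 at 0.9663. On the scaled values of the tested genes that replicate 1 pair stood at 0.9778, below the uninfected mutant replicates at 0.9782.

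The mutated gene itself, hlh-30 (WBGene00020930, chromosome IV, 4014772 to 4028123, in the coordinates of the deposited tables, whose genome build is not given in the sources used here), was read in every library. In uninfected wild type it stood at 59.2 and 49.1 scaled FPKM (54.1 ± 7.12, SD, n = 2) and in infected wild type at 79.2 and 88.5 (83.9 ± 6.55, n = 2). In the mutants it stood at 30 and 22.8 on control plates (26.4 ± 5.12, n = 2) and at 28.5 and 27.4 on S. aureus (27.9 ± 0.764, n = 2). The level was lower in infected mutants than in infected wild type (log2 difference −1.55, SE 0.18, limma adjusted p = 0.00696). The call was lost without infected wild-type replicate 2 (−1.48) or infected mutant replicate 2 (−1.52). The difference between uninfected groups did not pass (−1.01, adjusted p = 0.165), nor did the change on infection in wild type (0.63, adjusted p = 0.107) or in mutants (0.09, adjusted p = 0.837). Nor did the difference between those changes (−0.54, adjusted p = 0.59) pass. The labels do not state which part of the gene the allele removes, so the presence of transcript in the mutants neither checks nor contradicts the labels. Its level did order the libraries by labelled genotype: every mutant library (22.8 to 30) lay below every wild-type library (49.1 to 88.5).

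**Figure D1:**
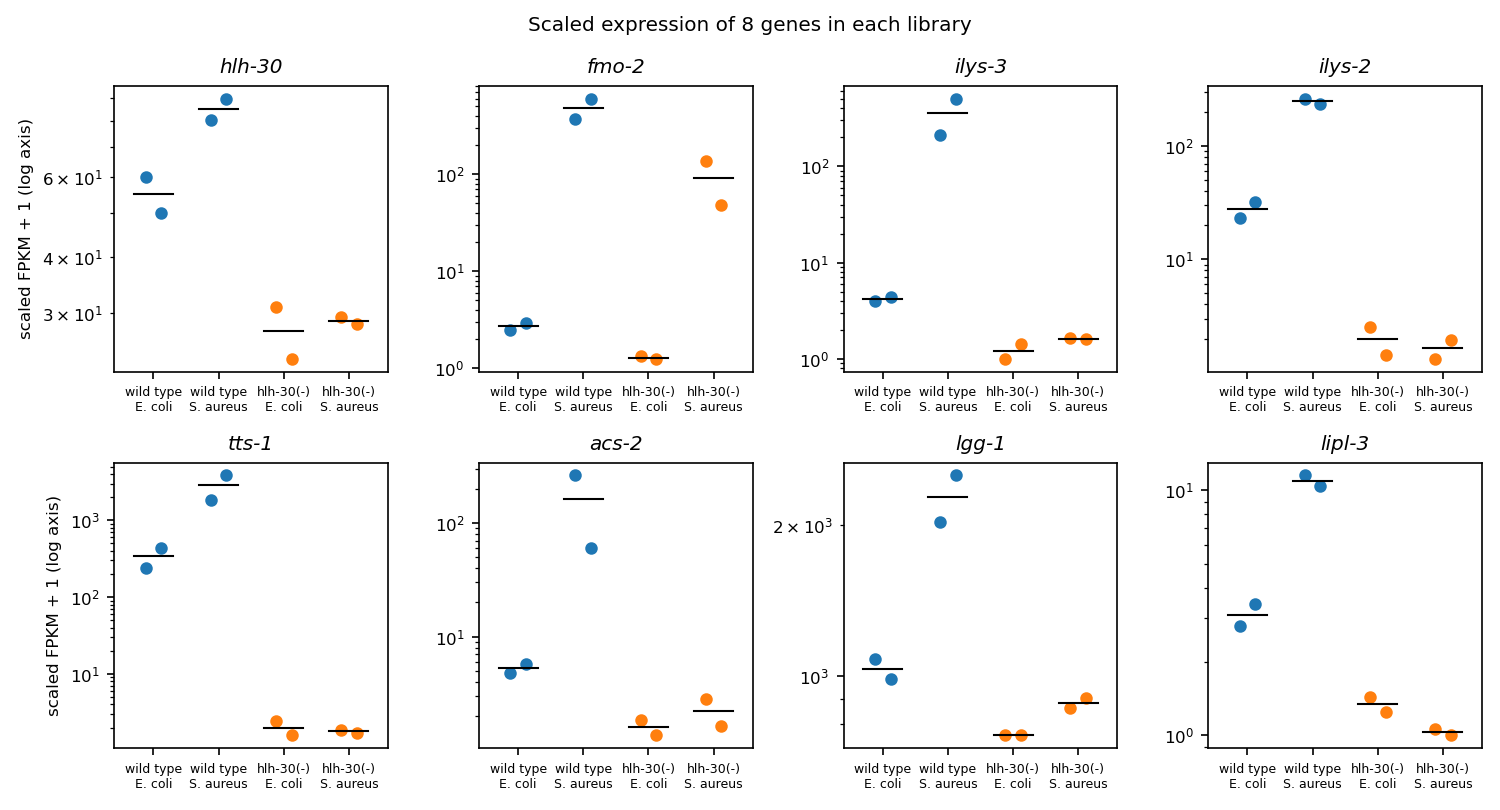
Scaled FPKM + 1 on a log axis for 8 named genes in the 4 groups, where each point is 1 library and each line the mean of the 2 libraries of a group. The ilys-3 libraries lie at a mean of 354 in infected wild type and 0.623 in infected mutants, while fmo-2 lies at 483 and 90.5.

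The first comparison asked which transcripts changed in wild-type animals on S. aureus. The flavin-containing monooxygenase gene fmo-2 went from 1.73 ± 0.324 to 483 ± 156 scaled FPKM (SD, n = 2), which is 173-fold on the log2(scaled FPKM + 1) scale (log2 change 7.44, SE 0.45, limma adjusted p = 1.31e-03). Transcripts of ilys-3, an invertebrate-type lysozyme that degrades bacterial cell walls, went from 3.20 ± 0.275 to 354 ± 203 (log2 change 6.27, SE 0.39, adjusted p = 1.31e-03). The acyl-CoA synthetase gene acs-2, which feeds fatty acids into mitochondrial oxidation, rose 24.2-fold (log2 4.60), and a second invertebrate-type lysozyme gene, ilys-2, rose 9.11-fold (log2 3.19). Cytochrome P450 genes, whose products oxidise foreign and endogenous small molecules, were among the 8 steepest decreases: cyp-33A1 fell from 291 ± 49 to 12.4 ± 5.09, with cyp-35C1 and cyp-35A3 at log2 changes of −3.71 and −3.68. In all, 271 genes rose and 161 fell, 347 of these 432 by at least 2-fold.

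Increases in wild type included host-defence and autophagy genes. Among 11 genes known before from responses to S. aureus, 3 rose (fmo-2, ilys-3 and cpr-2, a cathepsin B-like protease gene, at log2 2.69), none fell and 8 did not pass, while adjusted over the list alone 8 rose. The markers not passing were exc-5 (1.35), cyp-37B1 (2.0), F53A9.8 (1.56), clec-52 (1.16), clec-60 (1.63), Y65B4BR.1 (0.93), lys-5 (0.45) and clec-71 (−0.51). Their test against the other genes (limma's camera, preset correlation) gave an upward call (adjusted p = 5.28e-07), with adjusted p = 0.322 with an estimated correlation. Of 12 lysozyme genes, 3 rose, including ilys-4 (1.05), and 9 did not pass, and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.0338, and adjusted p = 0.638 with an estimated correlation). That upward call was lost without infected wild-type replicate 1 (adjusted p = 0.493) or uninfected wild-type replicate 1 (0.0715). Of 26 autophagy genes, 4 rose and 22 did not pass, among them the ubiquitin-like autophagosome genes lgg-1 (1.13) and lgg-2 (1.22) and the cargo receptor gene sqst-1 (1.36), and adjusted over the list alone 6 rose (adjusted p = 4.82e-05, and adjusted p = 0.533 with an estimated correlation). Of 23 antimicrobial peptide genes, nlp-29 (1.56) and cnc-10 (1.00) rose and 21 did not pass, against 8 that rose when adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.429 with an estimated correlation). Single members of other groups also rose: the lysosomal lipase gene lipl-3 (1.82), the insulin-like peptide gene ins-12 (3.00), and the nuclear receptor genes nhr-47 (2.16) and nhr-101 (1.57). The fourth autophagy gene, epg-9 (1.12), is named after its value was seen.

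Decreases included detoxification, secretory-pathway, lipid-synthesis and collagen genes. Tissue lists were called downward as well: none of 26 germline and oocyte genes passed, but their median was −0.55 (adjusted p = 2.24e-06, and adjusted p = 0.533 with an estimated correlation). Of 13 epidermis genes, wrt-10 fell and nlp-29 rose (median −0.38, adjusted p = 0.0123, and adjusted p = 0.533 with an estimated correlation), a call lost without uninfected wild-type replicate 1 (adjusted p = 0.0582). Of 50 cytochrome P450 genes, 8 fell, none rose and 42 did not pass, against 4 that rose and 13 that fell when adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.322 with an estimated correlation), and the call was lost without infected wild-type replicate 1 (adjusted p = 0.167). Of 53 UDP-glucuronosyltransferase genes, which attach sugars to small molecules, 5 fell, with ugt-16 at −3.01 and ugt-22 at −2.57, and 1 rose (adjusted over the list alone 14 fell and 2 rose; adjusted p = 1.93e-05, and adjusted p = 0.322 with an estimated correlation). Of 21 endoplasmic reticulum stress genes, 6 fell and 15 did not pass, including the protein disulfide isomerase genes pdi-2 (−1.50) and pdi-6 (−1.47) and the choline kinase gene ckb-2 (−2.0), and adjusted over the list alone 11 fell (adjusted p = 2.24e-06, and adjusted p = 0.331 with an estimated correlation). Of 12 target genes of the PMK-1 MAP kinase pathway, irg-4 (−2.57), irg-5 (−2.0) and mul-1 (−1.29) fell and 9 did not pass, and adjusted over the list alone 6 fell (adjusted p = 1.63e-05, and adjusted p = 0.322 with an estimated correlation). Of 23 genes of fatty acid synthesis and desaturation, 4 fell, including the stearoyl-CoA desaturase gene fat-7 (−3.22) and acs-1 (−2.24), and 2 rose, with 5 and 3 adjusted over the list alone. Its downward call (adjusted p = 0.00253, and adjusted p = 0.604 with an estimated correlation) was lost without infected wild-type replicate 2 (adjusted p = 0.0537). Of 130 collagen genes, 4 fell, with dpy-8 at −2.01 and sqt-3 at −1.37, and 126 did not pass, against 32 that fell when adjusted over the list alone (adjusted p = 1.84e-08, and adjusted p = 0.578 with an estimated correlation). A pair of C-type lectin genes listed with identical values in every library, F56A4.2 and Y19D10A.9, is treated as 1 uncertain item and stood at −3.02. Members of the counts of 5 or fewer named after their values were seen are ugt-54 (1.32), ugt-8 (−2.35), ugt-64 (−0.79), fat-3 (1.75), fat-4 (0.70), fat-5 (−1.79) and col-143 (−1.18).

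Both counts moved with single libraries. Without uninfected wild-type replicate 1, 3 genes rose and 6 fell, and without infected wild-type replicate 2, 28 rose and 24 fell. Rises and falls numbered 159 and 70 without uninfected wild-type replicate 2, 281 and 264 without infected wild-type replicate 1, and 140 and 97 or 135 and 93 without uninfected mutant replicates 1 or 2. Of the 69 named genes called in wild type, 62 lost the call without uninfected wild-type replicate 1, 47 without infected wild-type replicate 2 and 30 without uninfected wild-type replicate 2. The call was lost by 20 and 19 without uninfected mutant replicates 2 and 1, 10 without infected wild-type replicate 1 and 7 without either infected mutant library. None changed sign, and fmo-2, ilys-3, cyp-33A1, cyp-35C1, cyp-35A3 and gst-5 held the call without any 1 library. Of the 69, 7 held it in every alternative. The largest increases also included M03D4.3 and F15E6.10, listed at 0 in uninfected wild type with at most 5 and 6 recovered reads in infected animals. The largest decreases included Y50D4B.1, which had 1 read in each uninfected and was listed at 0 in each infected wild-type library.

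The second comparison asked the same of hlh-30 mutants, in which 13 genes rose and 50 fell on S. aureus. The monooxygenase gene fmo-2 rose from 0.294 ± 0.0561 to 90.5 ± 61.7 scaled FPKM (SD, n = 2; log2 change 5.96, SE 0.45, limma adjusted p = 3.73e-03). Desaturase genes of fat synthesis fell: fat-5 from 82.6 ± 3.35 to 1.88 ± 1.48 (log2 change −4.96, SE 0.36, adjusted p = 3.66e-03), fat-6 from 334 ± 36.8 to 37.5 ± 16 (−3.18) and fat-7 to 1.51 ± 0.225 (−4.51). The lysosomal lipase gene lipl-1 fell 17.8-fold and cyp-33A1 fell 30.8-fold. Lysozyme gene ilys-3 stood at 0.210 ± 0.297 and 0.623 ± 0.00737 on control and S. aureus plates (log2 0.45, adjusted p = 0.602).

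Some secretory, lipid and digestive genes fell in the mutants, in lists of which most members did not pass. Tissue markers moved in the same comparison without a member passing: 17 intestine genes had a median of −0.87 (adjusted p = 3.41e-09, and adjusted p = 0.258 with an estimated correlation). For 12 pharynx genes it was 1.12 (adjusted p = 4.87e-06, and adjusted p = 0.258 with an estimated correlation). Of 23 fatty acid synthesis genes, 4 fell and 19 did not pass, and adjusted over the list alone 12 fell (adjusted p = 8.4e-09, and adjusted p = 0.258 with an estimated correlation). Of 21 endoplasmic reticulum stress genes, 6 fell, with ckb-2 at −2.70, pdi-6 at −1.78 and pdi-2 at −1.67, and 13 fell adjusted over the list alone (adjusted p = 3.22e-11, and adjusted p = 0.242 with an estimated correlation). Of 21 cathepsin-type protease genes, asp-12 fell (−3.39) and 20 did not pass, against 14 that fell adjusted over the list alone (adjusted p = 6.46e-08, and adjusted p = 0.258 with an estimated correlation). Of 50 cytochrome P450 genes, 5 fell, including cyp-35A4 (−2.88) and cyp-35A3 (−2.81), and adjusted over the list alone 7 fell and 1 rose (adjusted p = 7.85e-06, and adjusted p = 0.242 with an estimated correlation). Of 22 saposin-like genes, whose products include pore-forming antibacterial proteins, spp-23 (−2.76) and spp-18 (−1.62) fell and 20 did not pass, against 7 adjusted over the list alone (adjusted p = 1.89e-05, and adjusted p = 0.283 with an estimated correlation). The PMK-1 target irg-5 (−2.74), the glucocerebrosidase gene gba-1 (−1.57), ugt-16 (−1.97), gst-5 (−1.49) and cdr-1 (−1.70) also fell, as did, named after their values were seen, acs-1 (−2.42), cyp-35C1 (−2.76) and cyp-35A2 (−1.89) of the lists above. Of the 11 known S. aureus markers, fmo-2 rose and 10 did not pass, with values of 0.06 for cpr-2, −0.10 for exc-5, −0.98 for lys-5, −0.19 for cyp-37B1, 1.04 for clec-60, −0.09 for clec-52, −0.92 for F53A9.8, −1.45 for clec-71 and −2.67 for Y65B4BR.1. Of these, cpr-2 turned to −0.084 under quantile normalization, and exc-5 and clec-52 to 0.050 and 0.073 with FPKM as deposited. The marker list's median of −0.10, with a mean of 0.10 and a downward test (adjusted p = 0.564), also changed sign with scaling.

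Single libraries moved the mutant counts. Without infected wild-type replicates 1 or 2, 26 genes rose and 86 fell or 25 and 84, and without either uninfected wild-type library 9 rose and 27 fell. Rises and falls were 8 and 47 or 2 and 11 without infected mutant replicates 1 or 2, and 12 and 24 or 4 and 9 without uninfected mutant replicates 1 or 2. Of the 29 named genes called in mutants, 20 and 12 lost the call without uninfected mutant replicates 2 and 1, 19 and 11 without infected mutant replicates 2 and 1, 9 without either uninfected wild-type library and 1 without either infected wild-type library. Of the 29, 6 held it in every alternative. Low read support underlay much of the rise: 6 of the 13 genes had under 10 recovered reads in every library of the comparison. Among them were Y50D4B.1, ZC334.12 and Y43F8A.1, each listed at 0 in uninfected mutants with 1 read in each infected library, and EGAP2.2, listed at 0 in uninfected mutants with at most 2. Of the remaining named increases, K09H11.10 had at most 7 reads, and F36H12.18 and C08E3.13 had log2 changes of 2.02 and 1.72. The gene F10D2.8 fell in both genotypes, with log2 changes of −5.60 in mutants and −5.59 in wild type.

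The third comparison set uninfected mutants against uninfected wild type, where 7 genes were higher and 7 lower. The long non-coding RNA gene tts-1 fell from 338 ± 137 scaled FPKM in wild type to 0.991 ± 0.578 in mutants (SD, n = 2; log2 difference −7.38, SE 0.40, limma adjusted p = 1.79e-03). The lysozyme gene ilys-2 fell from 26.8 ± 6.61 to 0.970 ± 0.762 (−3.85, adjusted p = 0.0146). The nuclear receptor gene nhr-47 was 5.46-fold higher in mutants (13.3 ± 2.66 against 1.61 ± 0.391), with Y19D10A.7 (2.78), F56A4.9 (2.61), K05B2.4 (1.96) and F09E5.14 (1.81) also higher, and C08E3.1 (−1.69) and C08E3.13 (−1.67) lower. Of 12 lysozyme genes, ilys-2 was lower and 11 did not pass, against 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.00289, and adjusted p = 0.713 with an estimated correlation). That list's call was lost without uninfected wild-type replicate 2 (adjusted p = 0.0904) or uninfected mutant replicate 1 (0.0543), where its median of −0.59 became −0.52 and 0.03. Low-read genes made up the rest: M03D4.3 and fipr-20, listed at 0 in uninfected wild type with at most 4 and 1 reads in mutants, and Y50D4B.1, Y60A3A.23 and Y43F8A.1, listed at 0 in uninfected mutants with at most 1, 3 and 1 reads in wild type. Without uninfected wild-type replicates 1 or 2, no gene was higher and 1 or 2 were lower, without either uninfected mutant library none was higher and 1 was lower (limma; 1196 genes had an unadjusted p under 0.05 with every library in). Without either infected wild-type library 11 were higher and 9 lower, and without either infected mutant library 7 and 11. Of the 14 named genes called, 13 lost the call without uninfected wild-type replicate 1 or either uninfected mutant library, 12 without uninfected wild-type replicate 2, 2 without either infected wild-type library and 1 without either infected mutant library, and tts-1 held it without any 1 library but lost it with voom on recovered reads. None of the 14 held the call in every alternative.

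The fourth comparison set infected mutants against infected wild type. The non-coding RNA gene tts-1 was at 0.794 ± 0.111 scaled FPKM in mutants and 2849 ± 1399 in wild type (SD, n = 2; log2 difference −10.54, SE 0.40, limma adjusted p = 1.22e-04). The lysozyme genes ilys-3 (0.623 ± 0.00737 against 354 ± 203; −7.65, SE 0.39, adjusted p = 4.21e-04) and ilys-2 (0.638 ± 0.445 against 249 ± 17; −7.28, SE 0.33, adjusted p = 2.58e-04) were lower. So was acs-2 of fatty acid oxidation, at 1.21 ± 0.828 against 161 ± 143 (−5.89, SE 0.62, adjusted p = 5.41e-03). Lipase, cathepsin, saposin-like and desaturase genes were lower too, and 156 genes in all were higher and 382 lower in mutants, 442 of the 538 by at least 2-fold. With FPKM as deposited the split was 159 higher and 216 lower, 42.4% higher against 29%. The deposited values place the median of all genes 0.145 higher on the log2 scale in this comparison and 0.155 higher in that of infected with uninfected mutants, against −0.025 and 0.0047 after scaling.

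Lysosomal and antibacterial genes were among those lower in mutants, while other lists were called upward with the preset correlation. Among these, medians were 0.41 for the v-ATPase, the proton pump of lysosomes (camera adjusted p = 1.2e-05), and 0.82 for metallothionein and cadmium-response genes (0.00239). They were 0.60 for PMK-1 targets (0.00272), 0.47 for antimicrobial peptides (0.0123) and 0.16 for collagens (0.00106). No list was called with an estimated correlation (lowest adjusted p = 0.429). Tissue lists moved in the same comparison: of 17 intestine genes 4 were lower (median −0.50, adjusted p = 6.56e-05, and adjusted p = 0.429 with an estimated correlation). These 4 were cpr-1, cpr-6, asp-1 and elt-7, which are counted again in the lists of cathepsin-type proteases and regulators below. The intestine median ranged from −0.84 to −0.16 without 1 library. None of 30 major sperm protein genes passed, though their median was 0.68 (adjusted p = 1.68e-13, and adjusted p = 0.429 with an estimated correlation). Of 12 lysozyme genes, 6 were lower, including lys-4 (1578 ± 279 in wild type against 106 ± 62.2), and 6 did not pass, against 7 lower adjusted over the list alone (adjusted p = 5.33e-06, and adjusted p = 0.429 with an estimated correlation). Of 21 cathepsin-type protease genes, 10 were lower, with cpr-1 at −4.72, cpr-2 at −2.75 and cpr-4 at −2.34, and 11 did not pass, against 1 higher and 14 lower adjusted over the list alone (adjusted p = 3.69e-08, and adjusted p = 0.429 with an estimated correlation). Of 5 lipase genes, lipl-1 (−4.05), lipl-2 (−3.53) and lipl-3 (−3.41) were lower, against 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.000196, and adjusted p = 0.429 with an estimated correlation). Of 22 saposin-like genes, 8 were lower, including spp-2 (−4.94) and spp-1 (−2.39), against 2 higher and 12 lower adjusted over the list alone (adjusted p = 1.07e-05, and adjusted p = 0.429 with an estimated correlation). Of 26 autophagy genes, 4 were lower and 22 did not pass, among them lgg-1 (−1.36), lgg-2 (−1.02) and epg-9 (−1.68), a component of the complex that starts autophagosome formation, against 10 adjusted over the list alone (adjusted p = 1.22e-06, and adjusted p = 0.429 with an estimated correlation). Of 23 lysosomal membrane and hydrolase genes, the DNase gene nuc-1 (−1.78) and the membrane genes scav-3 (−1.07) and lmp-1 (−0.83) were lower and 20 did not pass, against 6 adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.436 with an estimated correlation). That list's median of −0.15 became 0.035 with FPKM as deposited, and its call was lost without infected wild-type replicate 2 (adjusted p = 0.186) or infected mutant replicate 1 (0.0940). The intestinal cathepsin genes cpr-6 (−1.89) and asp-1 (−1.40) were lower. Of the 11 S. aureus markers, 6 were lower, including lys-5 (−3.31), F53A9.8 (−3.10), cyp-37B1 (−2.73) and fmo-2 (−2.55), and 5 did not pass, against 10 adjusted over the list alone (adjusted p = 1.45e-10, and adjusted p = 0.429 with an estimated correlation).

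A few regulators and lipid-synthesis genes were also lower in infected mutants, while most members of their lists did not pass. Of 29 regulators of immunity and lipid homeostasis, the basic helix-loop-helix genes mdl-1 (−4.14) and mxl-3 (−2.81) and the intestinal GATA factor gene elt-7 (−1.14) were lower and 26 did not pass, against 4 adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.429 with an estimated correlation), a call lost without infected mutant replicate 2 (adjusted p = 0.0718). Of 164 nuclear hormone receptor genes, 10 were lower, with nhr-99 at −2.49 and nhr-193 at −2.18, and 20 adjusted over the list alone (adjusted p = 5.55e-05, and adjusted p = 0.429 with an estimated correlation). Of 23 fatty acid synthesis genes, fat-5 (−3.62), fat-6 (−3.45), fat-3 (−1.55) and fat-4 (−0.83) were lower, and 4 adjusted over the list alone (adjusted p = 0.00188, and adjusted p = 0.429 with an estimated correlation), a call lost without infected wild-type replicate 1 (adjusted p = 0.141). The muscle genes unc-15 (−1.35), which encodes paramyosin, tnt-2 (−1.14) and mlc-2 (−0.74) were lower among 14 measured. Higher in mutants were the uncertain lectin pair F56A4.2 and Y19D10A.9 (3.23), D1086.3 (3.03), Y49G5A.1 (3.00), pals-6 (3.02), the collagen genes col-101 (2.54), col-137 (2.42) and col-143 (1.56), the PMK-1 target irg-4 (2.40) and the antimicrobial peptide genes nlp-27 (1.92) and nlp-24 (1.15), while nlp-28 was lower (−2.01). Of these lists, fat-4, atg-18 (−0.80) and col-8 (1.36) are named after their values were seen. Without infected mutant replicates 2 or 1, 17 genes were higher and 67 lower or 57 and 221, without infected wild-type replicate 2, 23 and 90, and without uninfected mutant replicate 2, 110 and 252. Of the 75 named genes called, 46 and 17 lost the call without infected mutant replicates 2 and 1, 45 and 19 without infected wild-type replicates 2 and 1, 12 without either uninfected mutant library, and 6 and 5 without uninfected wild-type replicates 1 and 2. Of the 75, 23, including tts-1, ilys-3, ilys-2, acs-2, spp-2, lys-4, lipl-1, lipl-3, fat-5, fat-6 and lgg-1, held it in every alternative.

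**Figure D2:**
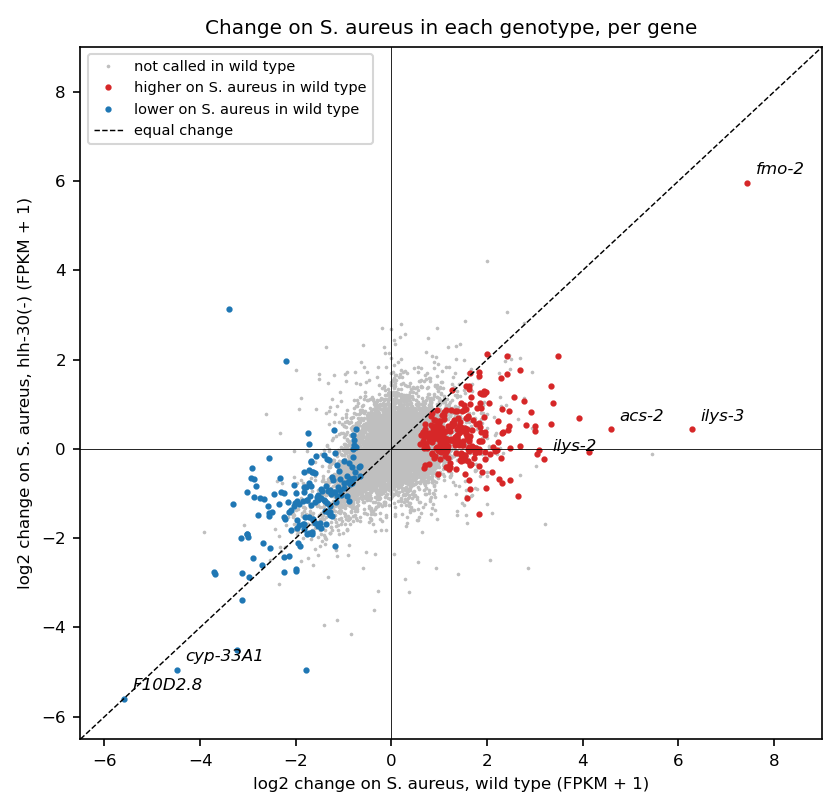
Log2 change on S. aureus in hlh-30 mutants (y axis) against that in wild type (x axis), where each point is 1 of the 14360 genes tested, coloured points are genes called in wild type (271 higher, 161 lower), and the dashed line marks equal change. The 271 genes lie at a median of 1.41 in wild type and 0.27 in mutants, and the 161 at −1.69 and −1.09.

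The last comparison tested whether the response to S. aureus differed between genotypes. By gene, ilys-3 was the 1 gene whose change was lower in mutants (0.45 against 6.27 in wild type; interaction −5.83, SE 0.56, limma adjusted p = 0.0404). That call was lost without either uninfected wild-type library (−5.75 and −5.89), either uninfected mutant library (−6.08 and −5.56) or infected mutant replicate 2 (−5.82). It was also lost with a pseudocount of 0.1, with FPKM of at least 5 or no filter, with FPKM as deposited, under quantile normalization and with the recovered reads, and no single isoform had a lower interaction, so the split of 2 higher and 1 lower became 2 and 0 under both scalings. Higher interactions were called for Y50D4B.1 (6.54) and Y43F8A.1 (4.17), which had no more than 1 recovered read in any library. The call of Y50D4B.1 was the only 1 of the 3 held in every alternative that tested it. Neither setting on recovered reads tested that gene, so a call held in this way does not show read support. The call of Y43F8A.1 was lost without infected mutant replicate 2 (4.14), uninfected wild-type replicates 1 or 2 (4.07 and 4.31) or uninfected mutant replicates 1 or 2 (4.16 and 4.21). The interactions of ilys-2 (−3.43, adjusted p = 0.136), lipl-3 (−2.20, adjusted p = 0.136), acs-2 (−4.16, adjusted p = 0.206), lgg-1 (−0.92, adjusted p = 0.218) and fat-5 (−3.17, adjusted p = 0.136) did not pass, and these 5 were picked after their values were seen. In simulated data the test recovered 10.4%, 55.2% and 78.8% of interactions of log2 1, 2 and 3. With 101 calls there against 3 here, the adjusted threshold was looser in the simulation, so these shares may overstate recovery here. In the real data 1322 of 14360 genes had an unadjusted p under 0.05. Without infected mutant replicate 1, 12 interactions were lower, without infected wild-type replicate 2, 5, and without either uninfected wild-type library, either uninfected mutant library or infected mutant replicate 2, 1 was higher and none lower.

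As sets, the genes that rose in wild type changed less in mutants, and the few that rose in mutants changed less in wild type. The 271 genes had a median log2 change of 1.41 in wild type and 0.27 in mutants, with the same sign in 202. Either infected mutant library against the mean of both uninfected ones gave 0.26 and 0.29. Within mutant replicate sets 1 and 2 the medians were 0.21 and 0.33. Of the 212 that rose at least 2-fold, 173 changed by under 0.5 times as much in mutants on that scale. The 161 genes that fell had medians of −1.69 and −1.09, with the same sign in 151. Chosen the other way, the 13 genes that rose in mutants had a median of 1.97 there and 0.055 in wild type, where 8 of the 12 with at least a 2-fold rise changed by under 0.5 times as much. The 50 that fell in mutants had medians of −1.90 there and −1.38 in wild type. Genes chosen in wild type lie farther from 0 there by the choice alone, so the genes were also chosen in 1 wild-type replicate set and measured in the other. The increases then had medians of 1.24 and 1.00 in wild type against 0.28 and 0.14 in the mutant set of the same number and 0.12 and 0.64 in the other mutant set. The decreases had medians of −1.70 and −0.99 against −0.96 and −1.14 or, in the other mutant set, −0.86 and −1.83. Without uninfected wild-type replicate 1 the mutants' median was 0.84 over the 3 genes that rose and −2.79 over the 6 that fell, and without infected wild-type replicate 2 it was 0.52 over the 28 that rose. Of the 271 genes, 112 were also lower in infected mutants than in infected wild type, where independent lists would share 7.21, but since both comparisons use the infected wild-type libraries, part of the overlap may come from them. In simulated unchanged groups, lists of the same lengths were taken from the top of each ranking, called or not. These shared 84.0 on average and at most 103 in 100 simulations. Of the 161 genes that fell, 29 were higher in infected mutants than in infected wild type, where the simulated lists shared 37 on average (at most 48). The simulated groups held no infection effect, so neither average is the overlap that called genes would share without a genotype effect. Between comparisons that share no library, 31 genes fell in both genotypes and 4 rose in both, against 0.561 and 0.245 for independent lists. These comparisons use the same estimate of each gene's spread, so their lists are not independent even without a shared library.

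**Figure D3:**
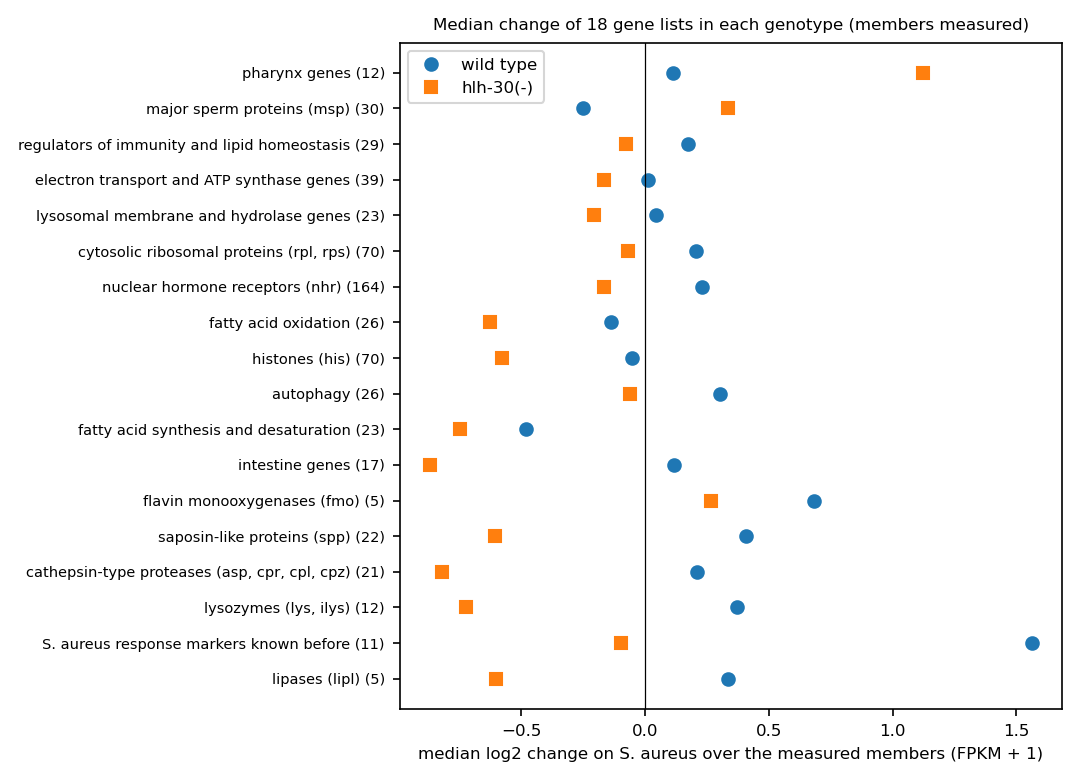
Median log2 change on S. aureus (x axis) of the members of 18 fixed gene lists (y axis) in wild type and in hlh-30 mutants, for the lists whose interaction was called with the preset correlation. The S. aureus markers lie at 1.56 and −0.10, lysozymes at 0.37 and −0.72, and major sperm protein genes at −0.25 and 0.33. Under other scalings the mutants' medians of the markers, autophagy genes, ribosomal protein genes and regulators change sign. Without 1 library, so do the wild-type medians of sperm protein genes (to 0.04, without uninfected wild-type replicate 1), cathepsin-type proteases (to −0.082), pharynx genes (to −0.20), intestine genes (to −0.18), histones (to 0.13) and electron transport genes (to −0.057). In mutants those of markers (to 0.065), autophagy genes (to 0.012), regulators (to 0.036) and ribosomal protein genes (to 0.0023) change sign.

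By list, 18 of 45 had an interaction call with the preset correlation and none had one otherwise (lowest adjusted p = 0.436 with an estimated correlation). Known S. aureus markers had a median interaction of −1.48 (0 of 11 positive), lysozymes −1.29, lipases −2.20, cathepsin-type proteases −0.85, saposin-like genes −0.75 and autophagy genes −0.51, with adjusted p of 2.87e-10, 2.56e-06, 4.92e-06, 1.46e-06, 1.7e-07 and 2.11e-06 from camera, and each of these 6 kept its call without any 1 library. Tissue markers were among the other 12 lists called: intestine genes had a median interaction of −0.67 (adjusted p = 6.26e-05, and adjusted p = 0.512 with an estimated correlation) and pharynx genes 0.97 (adjusted p = 0.000199, and adjusted p = 0.436 with an estimated correlation). The marker median became −2.23 without infected mutant replicate 1, that of lysozymes −0.77 without infected mutant replicate 2, and that of cathepsin-type proteases −0.49 without uninfected mutant replicate 2. Adjusted over the list alone, 8 markers, 7 lysozymes, 3 lipases, 7 cathepsin-type proteases, 6 saposin-like genes and 3 autophagy genes had a lower interaction.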

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

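Of the tests weighed here, those of gene choice, scaling and exposure for the smaller mutant response, of scaling, of the wild-type part and by replicate set for the sperm protein genes, and of single reads were chosen only after the result was seen.

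Responses to S. aureus that differed between genotypes by the interaction test were ilys-3 (−5.83), Y43F8A.1 (4.17) and Y50D4B.1 (6.54) among genes. Among lists, the median interaction was negative for S. aureus markers (−1.48), lysozymes (−1.29), lipases (−2.20), saposin-like genes (−0.75), cathepsin-type proteases (−0.85), autophagy genes (−0.51), intestine genes (−0.67), nuclear hormone receptors (−0.37), histones (−0.45), cytosolic ribosomal proteins (−0.29), and regulators of immunity and lipid homeostasis (−0.16). It was also negative for flavin monooxygenases (−0.74), fatty acid synthesis (−0.51), fatty acid oxidation (−0.43), lysosomal membrane and hydrolase genes (−0.27) and electron transport genes (−0.18), and positive for major sperm proteins (0.57) and pharynx genes (0.97). None of the 18 was called by camera with an estimated correlation (lowest adjusted p = 0.436), and the ribosomal call was lost under quantile normalization (median −0.0060). With FPKM as deposited the medians were −0.15 for ribosomal proteins, −0.034 for electron transport, −0.13 for lysosomal genes and −0.014 for regulators. Calls were lost without 1 library for flavin monooxygenases (adjusted p = 0.208, 0.0636, 0.0518 and 0.139 without infected wild-type replicate 2, uninfected wild-type replicate 2, infected mutant replicate 1 and uninfected mutant replicate 1), lysosomal genes (0.0622 without uninfected mutant replicate 2), fatty acid oxidation (0.0790 without uninfected wild-type replicate 2) and regulators (0.0811 and 0.0865 without uninfected wild-type and infected mutant replicate 2). Fatty acid synthesis lost its call without infected wild-type replicate 1 (median 0.03) or uninfected wild-type replicate 2 (−0.10), and electron transport lost it without infected wild-type replicate 1 (−0.13), uninfected wild-type replicate 2 (−0.09), infected mutant replicate 2 (−0.11) or uninfected mutant replicate 2 (−0.12). Medians also moved by over 1.5 times without infected wild-type replicate 1 for flavin monooxygenases (−1.34), and without infected wild-type replicate 2 for flavin monooxygenases (−0.16), fatty acid oxidation (−0.11) and fatty acid synthesis (−0.79). Without infected mutant replicate 1 they moved for markers (−2.23), lysosomal genes (−0.14) and electron transport (−0.27), and without infected mutant replicate 2 for lysozymes (−0.77), lysosomal genes (−0.43) and fatty acid synthesis (−0.12). Without uninfected wild-type replicate 1 they moved for major sperm proteins (0.30) and electron transport (−0.29), and without uninfected wild-type replicate 2 for major sperm proteins (0.87) and histones (−0.68). Without uninfected mutant replicate 1 electron transport stood at −0.28, and without uninfected mutant replicate 2 major sperm proteins stood at 0.37, cathepsin-type proteases at −0.49 and fatty acid synthesis at −0.25.

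The genes that rose in wild type on S. aureus changed less in hlh-30 mutants, while those that fell changed more alike. Scaling as the whole cause was argued against: the mutant median was at most 0.242 of the wild-type median under the other scalings. The slope of mutant on wild-type change was higher for the genes that fell than for those that rose. The difference was at least 0.384 in each of the 4 pairs of an infected with an uninfected mutant library, which share libraries. A uniformly weaker exposure of the mutants would lower both slopes alike only if both sets of genes followed exposure to the same degree. The control also differed in bacterial species, so the slopes do not decide on such an exposure. Choosing and measuring genes in the same wild-type libraries stays open in part: with genes chosen in 1 wild-type set, the wild-type median in the other set was above the mutant median in all 4 combinations of sets, but by 0.363 to 1.11, which differ by more than the smallest. Weaker exposure stays open, as do dependence on hlh-30, other differences in infection between genotypes and the share of tissues, which were not tested.

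Major sperm protein genes had negative changes in wild type (median −0.25) and positive ones in mutants (0.33) on S. aureus, neither called by camera otherwise (adjusted p = 0.709 and adjusted p = 0.519 with an estimated correlation). Without uninfected wild-type replicate 1 the wild-type median was 0.04 and the interaction 0.30, without uninfected wild-type replicate 2 the interaction was 0.87, and without uninfected mutant replicate 2 it was 0.37 and the mutant call was lost (median 0.10, adjusted p = 0.0621). Scaling as the cause was argued against by an interaction median of at least 0.618 under other scalings, and of at least 0.348 there without any 1 library (SD over members 0.113). That SD is over family members, which moved together, and does not measure the spread between libraries. A different sperm content of the animals and reads shared between near-identical family members cannot be told apart with the 25 sperm genes outside the family that were examined: their median interaction of 0.333 (80% positive) met bounds that left out the spread between replicates, and it was −0.010 (12 of 25 positive) in replicate set 1 and 0.80 (23 of 25) in set 2. Their wild-type median was 0.028, and lay above the family's by 0.52 in set 1 and by 0.097 in set 2, which decides nothing, and age or stage of the animals stays open too.

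The interaction calls of Y50D4B.1 and Y43F8A.1 may come from single reads without spread between replicates: no library held more than 1 recovered read of either. Both had 1 read in each uninfected wild-type and each infected mutant library and were listed at 0 in the other 4. They were 2 of 7 tested genes with 1 read in each of 4 libraries and none elsewhere. None of the 7 had the opposite pattern, and 0.1 would be expected per pattern. The 2 genes were found through this pattern, so that count decides nothing. Neither gene was tested among genes with at least 10 reads in 2 libraries, and no biological explanation was tested.

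Genes left out of the report's tests because an isoform estimate had a failed status gave calls when kept, among 191 such genes. In wild type on S. aureus, alh-1 (1.09), unc-43 (0.85), fbxl-1 (1.75), F26F12.3 (1.6), Y39G10AR.11 (1.49) and pmt-1 (1.36) stood higher. Between uninfected genotypes, C09D4.1 stood lower (−2.52) and mrpl-24 higher (1.67) in mutants. Between infected genotypes, deg-1 (2.21) and mrpl-24 (1.85) stood higher in mutants, and alh-1 (−1.2), mec-7 (−1.82), pyp-1 (−1.06), pck-2 (−0.94), fbxl-1 (−2.66), C09D4.1 (−2.35), F26F12.3 (−1.70), R02F2.1 (−1.24) and Y39G10AR.11 (−1.49) stood lower.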

How the results depend on the processing

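The filter of at least 10 recovered reads, voom on recovered reads, and choosing genes in 1 wild-type set and measuring them in the other and in either mutant set were chosen after the data were seen. Apart from left-out libraries, 177 of 228 values for the main results stayed alike. Counts, most of the values, had to stay within 1.5 times and could not reverse. Median changes had to stay within the SD between infected mutant libraries, and hlh-30 had to keep its sign and side of the threshold. No such median and no hlh-30 value changed sign, while markers that had not passed did, as given below. The cause of the main values that moved was not tested, except that single isoforms and single contrasts leave fewer reads or libraries per test.

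Counts that moved, higher and lower, were as follows. In wild type on S. aureus they were 147 and 88 with no filter, 58 and 54 for single isoforms and 11 and 11 with only the libraries of the contrast. In mutants on S. aureus, 4 were higher with voom and 8 with only the contrast's libraries, and 19 lower with no filter, 22 for single isoforms and 13 with only the contrast's libraries. Between uninfected genotypes, 2 were higher with no filter, 0 for single isoforms and 2 with voom, and 3 lower for single isoforms, 3 with at least 10 reads and 0 with voom. Between infected genotypes, 101 and 236 differed with no filter, 54 and 160 for single isoforms and 79 and 167 with only the contrast's libraries, and 216 were lower with FPKM as deposited. Interactions were 1 and 0 with FPKM of at least 5, 5 and 2 with no filter, 0 and 0 with at least 10 reads or voom (limma; 1290 and 1239 genes at an unadjusted p under 0.05), and 0 lower with a pseudocount of 0.1, FPKM as deposited, quantile normalization or single isoforms. Main counts were 271 and 161, 13 and 50, 7 and 7, 156 and 382, and 2 and 1. The filter of at least 10 reads called 324 and 205, 13 and 69, 5 and 3, and 185 and 427 in the first 4 comparisons, sharing 417 of the 432 genes, 56 of 63, 8 of 14 and 517 of 538, and voom called 317 and 231, 4 and 68, 2 and 0, and 178 and 458, sharing 385, 49, 2 and 475. No interaction fit was made with only a contrast's libraries, since that contrast uses all 8.

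The mutants' median change of genes higher in wild type was 0.30 with a pseudocount of 0.1, 0.29 with no filter, 0.37 with FPKM as deposited, 0.23 with at least 10 reads, 0.24 with voom, 0.14 and 0.64 for genes chosen in wild-type set 2 and measured in mutant sets 1 and 2, and 0.12 for genes chosen in set 1 and measured in mutant set 1. That of genes lower in wild type was −0.95 with FPKM as deposited, −1.23 with voom, −0.96 and −0.86 chosen in set 1 and measured in mutant sets 2 and 1, and −1.83 chosen and measured in sets numbered 2. The change of hlh-30 on infection in wild type passed with voom (0.67). In wild type the median of genes higher in mutants was 0 with no filter. In mutants cpr-2 stood at −0.084 under quantile normalization, exc-5 at 0.050 with FPKM as deposited, and clec-52 at 0.073 with FPKM as deposited and 0.0036 under quantile normalization.

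Leaving out 1 library gave 3 to 281 higher and 6 to 264 lower genes in wild type, 2 to 26 and 9 to 86 in mutants, 0 to 11 and 1 to 11 between uninfected genotypes, 17 to 139 and 67 to 303 between infected genotypes, and 1 to 3 and 0 to 12 for the interaction. The mutants' medians ranged from 0.23 to 0.84 and from −2.79 to −1.06, lists called in mutants from 19 to 31, and hlh-30 between infected genotypes from −1.64 to −1.48 and in mutants from −0.10 to 0.28. Markers that changed sign were Y65B4BR.1 in wild type (−0.16 to 2.02) and, in mutants, cpr-2 (−0.091 to 0.21), exc-5 (−0.25 to 0.065), cyp-37B1 (−0.77 to 0.38), clec-60 (−0.060 to 2.14) and clec-52 (−0.51 to 0.32).

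With the replicate number as a block, 31 genes were lower in mutants on S. aureus, the 1 count moved by over 1.5 times; the other counts were 260 and 151 in wild type, 13 higher in mutants, 6 and 7, 166 and 336, and 2 and 1, and 21, 29, 15, 29 and 18 lists were called. The labels do not say that a number marks a shared batch or day. Deviations of same-numbered libraries were correlated across genes over the 6 pairs of groups. The value was 0.23 between the infected groups of both genotypes and 0.09 between the uninfected groups. Between infected and uninfected animals it was 0.02 within wild type and −0.17 within mutants. Uninfected wild type with infected mutants gave 0.08, and infected wild type with uninfected mutants 0.0023.

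Depth limits low genes: 544 tested genes had under 10 recovered reads in every library, and calls with under 10 reads numbered 10 and 5, 6 and 1, 2 and 3, 12 and 6, and 2 and 0 in the 5 comparisons.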

Other observations

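Tests here were made only after the list values were seen, except the list tests, which were fixed beforehand.

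Tissue and housekeeping lists also moved. Of 12 pharynx genes, none passed over all genes in mutants on S. aureus (limma; 2332 genes had an unadjusted p under 0.05), but adjusted over the list alone 9 were higher, with a median log2 change of 1.12 (camera adjusted p = 4.87e-06, and adjusted p = 0.258 with an estimated correlation). In wild type the same list had a median of 0.11 and was not called (adjusted p = 0.505), and the list's interaction median was 0.97. Uninfected mutants started lower than uninfected wild type in this list (median −0.56, adjusted p = 0.0115, and adjusted p = 0.713 with an estimated correlation), a call lost without uninfected wild-type replicate 1 (adjusted p = 0.279) or uninfected mutant replicate 2 (0.204). Of 17 intestine genes, none passed over all genes in mutants on S. aureus and 9 fell adjusted over the list alone (median −0.87, adjusted p = 3.41e-09, and adjusted p = 0.258 with an estimated correlation). In wild type pgp-1 (−1.96) and pho-1 (−1.82) fell, and the list's median of 0.12, mean of −0.27 and downward test (adjusted p = 0.275) differed in sign. Of 70 histone genes, 4 were positive in mutants on S. aureus (median −0.58, adjusted p = 3.22e-11, and adjusted p = 0.242 with an estimated correlation). Uninfected mutants started higher than uninfected wild type (median 0.28, adjusted p = 3.35e-05, and adjusted p = 0.713 with an estimated correlation), a call lost without uninfected wild-type replicate 1 (adjusted p = 0.0595). The gene his-71, which encodes a replacement histone of the H3 family, was lower in infected mutants than in infected wild type (−1.60, limma adjusted p = 2.85e-03).

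Several lists differed in the same direction between genotypes on both kinds of plates. Proteasome subunit genes were lower in mutants in 32 of 33 members on control plates (median −0.27, adjusted p = 4.31e-10, and adjusted p = 0.713 with an estimated correlation) and had a median of −0.25 on S. aureus (adjusted p = 1.37e-05, and adjusted p = 0.465 with an estimated correlation). Cytosolic heat shock genes had medians of −0.55 and −0.68 (adjusted p = 1.06e-08 and 1.2e-05, and adjusted p = 0.713 and 0.429 with an estimated correlation). Genes of the v-ATPase, the proton pump of lysosomes, had positive medians of 0.24 and 0.41 in mutants (adjusted p = 0.000523 and 1.2e-05, and adjusted p = 0.713 and 0.429 with an estimated correlation), with the first call lost without uninfected wild-type replicate 2 (adjusted p = 0.202) or uninfected mutant replicate 2 (0.208). No member of these 3 lists passed over all genes with limma (1196 and 2932 genes had an unadjusted p under 0.05 in these comparisons). Of the 7 genes higher and 7 lower in uninfected mutants, 4 and 5 were also called in the same direction in infected mutants, which are other libraries, against 0.0760 and 0.186 for independent lists. Both comparisons use the same estimate of each gene's spread, so these lists are not independent.

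Genes near hlh-30 were counted because a mutant strain can carry other variants linked to its mutation. Within 1 Mb of hlh-30, 18 of 272 tested genes (6.62%) differed between infected genotypes, against 3.68% elsewhere (Fisher's exact test, two-sided p = 0.0218, adjusted over 4 tests 0.0870), which did not pass, and none of 272 differed between uninfected genotypes. On the whole of chromosome IV, 3.67% of 2504 genes differed between infected genotypes, against 3.75% elsewhere (Fisher's exact test, two-sided p = 0.908).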
